A study of Bos taurus with 20 samples.

How the data were processed

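Messenger RNA was measured in 20 endometrial biopsies of Holstein heifers, 4 animals on each of days 0, 5, 10, 14 and 18 of a synchronized cycle. Total RNA was extracted, poly(A) RNA was captured and libraries were made with a TruSeq stranded kit, per the labels' protocols. The submitters' processing notes name FastQC, STAR and edgeR, with no versions and no roles. The genome build, the annotation, the counting program and its strand setting are not given in the sources used here. Whether reads of a gene and its antisense partner, or of near-identical copies, could be told apart is therefore open. The values are raw counts per gene ID, 1 deposited file per library with 27607 IDs; they were whole numbers that summed to between 21234000 and 26644679 per library, and per the file headers each file holds 1 sample. No row without an ID and no column of another sample was found. Each library's day and number came from its own labels. The labels say that animals were assigned at random to a day, with 4 per day, so libraries of a day were treated as separate animals. Chi-square values per degree of freedom between libraries of a day ranged from 29.0 to 598 over 30 pairs, so no pair agreed within sampling noise.

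The deposited counts do not come with gene names, and 0 of the 27607 IDs matched the table of 37063 cattle genes used here. The rule fixed before the data were examined named the 8 largest rises and 8 largest falls per step among genes with adjusted p under 0.05, at least 5 CPM on average over the 8 libraries, no overlap between the days and a gene symbol, besides steroid and oxytocin receptors and members of fixed lists. With no names, this rule was reduced to at most 2 IDs that rose and 2 that fell: the 2 largest rises and the largest fall from day 0 to day 5 that met its other conditions, and the single ID that passed from day 5 to day 10. The tests of 30 fixed gene lists, a covariate for epithelium against stroma, and checks of GC content and gene length all need names or gene models and were not run.

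Counts were analysed in R 4.3.3 with edgeR 4.0.16. IDs with low counts were removed with filterByExpr, which left 16947. Libraries were scaled by TMM factors, dispersions were estimated over all 20 libraries (common biological coefficient of variation 0.445), and the quasi-likelihood model was fitted with the robust option and 1 mean per day. The 5 steps (day 0 to 5, 5 to 10, 10 to 14, 14 to 18 and 18 to 0) were tested with the quasi-likelihood F-test, as were all differences between the 5 days at once; p-values are two-sided and Benjamini-Hochberg adjusted over the tested IDs, with a threshold of 0.05. The remaining 5 of the 10 pairs of days were added after the data had been examined. CPM values used the TMM-scaled totals, and log2 CPM a prior count of 2. The SE of a log2 fold change was its size divided by the square root of F. Ratios of counts carry exact 95% binomial intervals, which cover counting error only, since the reads carry no molecular identifiers in the sources used here. Single values per library were compared with two-sided exact permutation tests (scipy 1.17.1, Python 3.11.15), for which 4 against 4 libraries cannot give a p below 0.0286. Figures were drawn with matplotlib 3.10.9.

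Alternatives fixed before the data were examined were RLE (median of ratios) factors or total counts alone, no low-count filter or at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma 3.58.1 voom with quality weights, a fit without the robust option, a block for the replicate number, only the 8 libraries compared, a test against a 2-fold change, and each library left out in turn. Counts without 3 or 4 libraries that lay apart, 10 or 100 in place of 50 abundant IDs, and other gene sets for the position between days 14 and 0 were added later, as were a check of the replicate numbers by 2000 permutations within days and positions with each day 0 library kept out of the choice of genes. The edgeR test was tested on simulated data drawn from the real means, library sizes and dispersions, with 200 IDs of at least 5 CPM changed by 2-fold or 4-fold. Apart from these changes, each ID had 1 mean and 1 dispersion over all 20 libraries, so every day had the same spread and no library stood apart. For day 0 to day 5, over 16790 IDs, it recovered 78% of the 4-fold and 25% of the 2-fold changes, with 4 false calls among 107. For day 18 to day 0, over 16812 IDs, it recovered 73% and 31%, with 5 false calls among 109. For all 5 days at once, over 16805 IDs, it recovered 78% and 24%, with 3 false calls among 105. On the same simulated counts for day 0 to day 5, DESeq2 made 29 false calls among 153 and voom 4 among 105.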

Results

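The series measured messenger RNA in the endometrium, the lining of the uterus, of virgin Holstein heifers through the estrous cycle. Its title and design text pose the question of how the secretory output of this tissue changes as the cycle recurs. The cycles were synchronized with hormones, and animals were assigned at random to a biopsy on day 0 (estrus, the time of sexual receptivity), 5, 10, 14 or 18, with 4 animals per day and 1 library per animal. In cattle, a corpus luteum that secretes progesterone grows after ovulation and regresses late in the cycle. The count tables held 27607 gene IDs for each of the 20 libraries, and 4586 IDs had no counts in any library. Total counts per library ranged from 22730313 to 26644679 on day 0, from 22462099 to 24686709 on day 5, from 21424619 to 23200131 on day 10, from 21610300 to 24589873 on day 14 and from 21234000 to 24274750 on day 18. The tables do not pair the IDs with gene names, and 0 of the IDs matched the name table used here. Genes are therefore described as groups, by the day and direction of their change, and only 4 IDs are printed.

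The 4 day 0 libraries lay close together, while those of days 10 and 18 were spread widely. The median correlation of log2 CPM (counts scaled to library size) across genes between libraries of a day was 0.973 on day 0, 0.952 on day 5, 0.882 on day 10, 0.969 on day 14 and 0.896 on day 18. Genes are not independent replicates, so these correlations only describe the libraries. The first principal component held 27.1% of the variance and the second 22.2%. Day 10 replicates 1 and 3 and day 18 replicate 3 had scores of 103, 119 and 117 on the first component, and the next highest score was 33.3 in day 14 replicate 4. Day 10 replicate 3 correlated best with day 18 replicate 3, at r = 0.975. Day 18 replicate 1 correlated best with day 0 replicate 2, at r = 0.956, and day 5 replicate 1 with day 18 replicate 2, at r = 0.957.

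**Figure D1:**
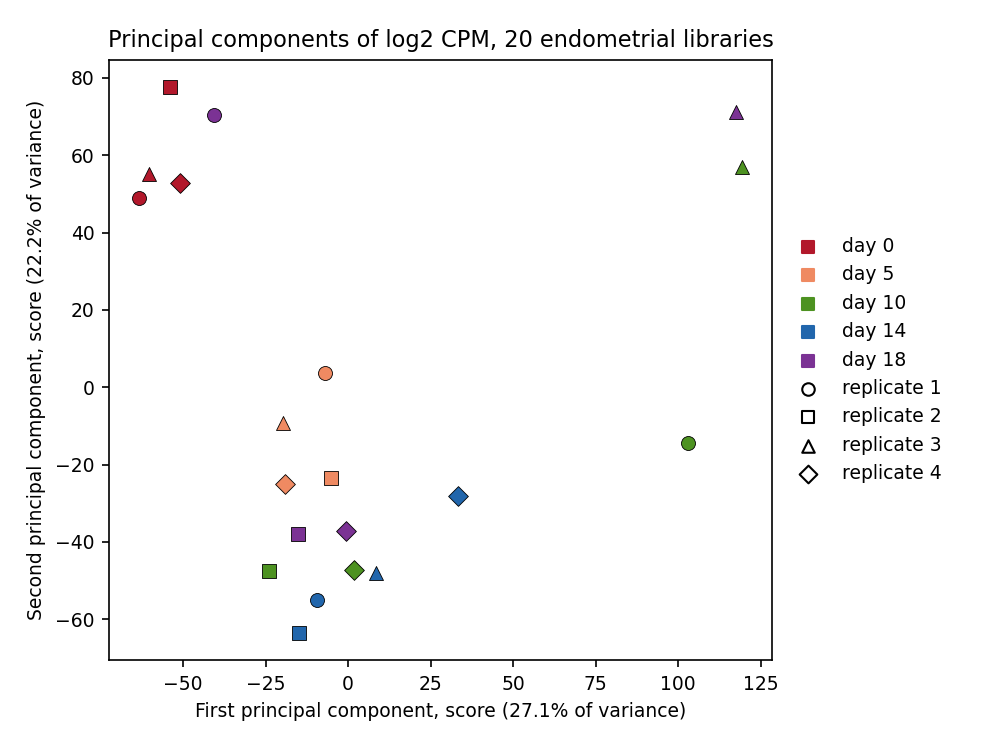
Scores of the 20 libraries on the first 2 principal components of log2 CPM (axes in score units), with color for the day and marker shape for the replicate number. Day 10 replicates 1 and 3 and day 18 replicate 3 lie at 103 or more on the first component, and day 18 replicate 1 lies with the 4 day 0 libraries at the upper left.

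A small set of transcripts took a larger part of the RNA on day 0 than on day 5. The 50 most abundant IDs of each library held 20.3% ± 0.579 of its counts on day 0 (SD, n = 4) and 13.4% ± 1.03 on day 5 (SD, n = 4), and all 4 day 5 libraries lay below all 4 day 0 libraries. The difference was −6.83 percentage points, with p = 0.0286 by a two-sided exact permutation test, the smallest p that 4 against 4 libraries allow. Over the 10 tests of this share and of the number of detected IDs it was 0.143 after Benjamini-Hochberg adjustment, so it did not pass 0.05. The share was 14.7% ± 3.53 on day 10, 11.4% ± 0.514 on day 14 and 16.2% ± 5.77 on day 18 (SD, n = 4 each). On day 18 it was 22.7% in replicate 3 (95% Wilson interval 22.67 to 22.71, counting error only) and 19.5% in replicate 1 (19.46 to 19.49), against 11.8% in replicate 2 and 10.97% in replicate 4. IDs at 1 CPM or more numbered 14504.5 ± 60.7 on day 0 and 14864.8 ± 160 on day 5 (SD, n = 4 each), with exact permutation p = 0.0286 and 0.143 after adjustment; all 4 day 5 libraries had more than any day 0 library. Of the 50 IDs most abundant on day 0, 34 were among the 50 most abundant on day 5, 28 on day 10, 30 on day 14 and 35 on day 18.

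**Figure D2:**
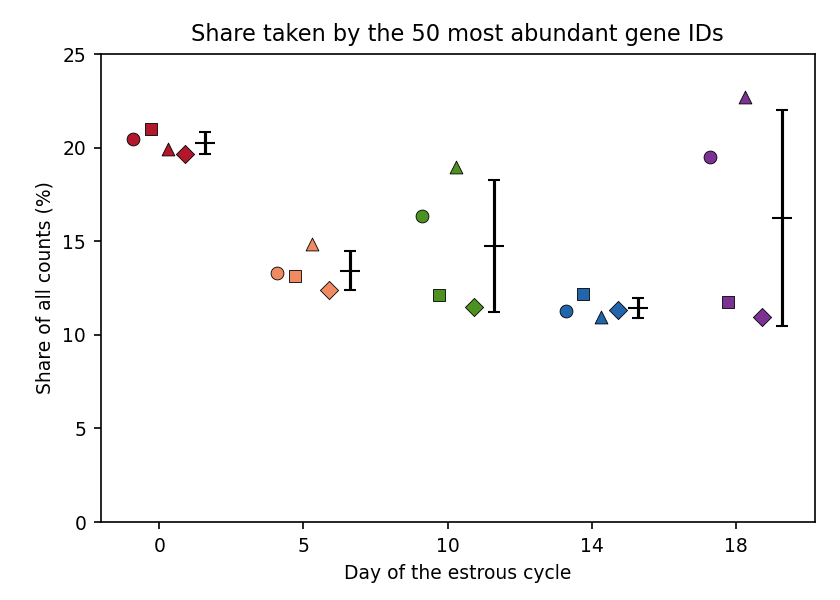
Share of each library's counts (percent, vertical axis from 0) held by its 50 most abundant gene IDs, by day; points are the 4 libraries of a day and the bars beside them the mean ± SD. Day 0 libraries lie at 20.3% ± 0.579 and day 14 libraries at 11.4% ± 0.514, while day 18 holds both 22.7% and 10.97%.

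From estrus to day 5, 751 genes rose and 702 fell among 16947 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 4 libraries per day). Of those that rose, 296 did so by at least 4-fold and 64 by at least 16-fold; of those that fell, 125 changed by at least 4-fold and 27 by at least 16-fold. The median log2 fold change was 1.68 among the genes that rose and −0.998 among those that fell. Relative to day 0, the mean log2 CPM of the genes that rose was 1.85 ± 0.446 on day 5, 1.48 ± 0.287 on day 10, 1.28 ± 0.127 on day 14 and 0.820 ± 0.335 on day 18 (SD, n = 4 libraries each). The genes that fell averaged −1.31 ± 0.0823 on day 5, −1.32 ± 0.171 on day 10, −1.19 ± 0.0599 on day 14 and −1.06 ± 0.206 on day 18. The genes were chosen on the day 0 and day 5 values and every mean is relative to the same day 0 libraries, so none of these means is independent of the choice. With each library scaled by its total count alone, 1732 genes changed and 79.0% of them rose, against 51.7% with the TMM factors (trimmed mean of M values) used throughout. That scaling put the median log2 fold change of all tested genes at 0.21 instead of 0.017. Leaving out day 0 replicates 1, 2, 3 or 4 lowered the count from 1453 to 578, 633, 897 or 607, and leaving out day 5 replicates 2, 3 or 4 lowered it to 434, 898 or 746; 43.5% to 44.6% of the genes rose without a day 0 library and 47.5% to 55.01% without a day 5 library. Against a 2-fold change instead of no change, 55 genes passed, and with only the 8 libraries of both days in the fit, 3519 did. DESeq2 called 2550 genes and limma voom with quality weights 5796.

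ENSBTAG00000055199 and ENSBTAG00000015533 had the largest rises among IDs with at least 5 CPM on average and no overlap between both days. ENSBTAG00000055199 had 3 counts in all 4 day 0 libraries together and 7318 on day 5, a ratio of 2261 after scaling (95% counting interval 773 to 10966). Its fitted log2 fold change, which depends on the prior count, was 10.91 (SE 2.51, edgeR adjusted p = 0.0147). Its mean was 73.8 ± 50.8 CPM on day 5 (SD, n = 4), then 20.3 ± 23.8, 3.59 ± 6.38 and 0.293 ± 0.318 CPM on days 10, 14 and 18. It reached 6 counts in day 5 replicate 1, against 2035 to 2663 in the other day 5 libraries, and 8 and 2 counts in day 10 replicates 1 and 3, against 1130 and 762 in replicates 2 and 4. Without day 0 replicate 1, 2 or 4 its edgeR adjusted p was 0.0536, 0.0511 or 0.0508; over its 19 alternatives it ranged from 4.94e-07 to 0.0749. ENSBTAG00000015533 went from 1 count on day 0 to 1673 on day 5, a ratio of 1551 (95% counting interval 278 to 61281), with a fitted log2 fold change of 9.99 (SE 1.93, edgeR adjusted p = 0.00624). Its mean was 16.8 ± 11.4 CPM on day 5 and 0.0540 ± 0.0819 CPM on day 18 (SD, n = 4 each), and day 5 replicate 1 had 2 counts against 467 to 612 in the others. Over 19 alternatives the log2 fold change of ENSBTAG00000015533 ranged from 9.21 to 11.6, the latter without day 0 replicate 2. With only the 8 libraries of both days, the low-count filter removed ENSBTAG00000055199 and ENSBTAG00000015533. That fit is therefore missing from the 19 alternatives of each. The largest fall was that of ENSBTAG00000037768, from 364 ± 288 CPM on day 0 to 1.43 ± 2.24 CPM on day 5 (SD, n = 4 each), a log2 fold change of −8.00 (SE 1.29, edgeR adjusted p = 0.00247). Over 20 alternatives this fold change ranged from −10.18, without day 5 replicate 1, to −7.27, without day 0 replicate 3. ENSBTAG00000037768 had 2 counts over the day 10 libraries, 3 over the day 14 libraries and a mean of 4.80 ± 5.73 CPM on day 18. From day 18 to day 0 it rose by a log2 fold change of 6.25 (SE 1.19, edgeR adjusted p = 0.0123).

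**Figure D3:**
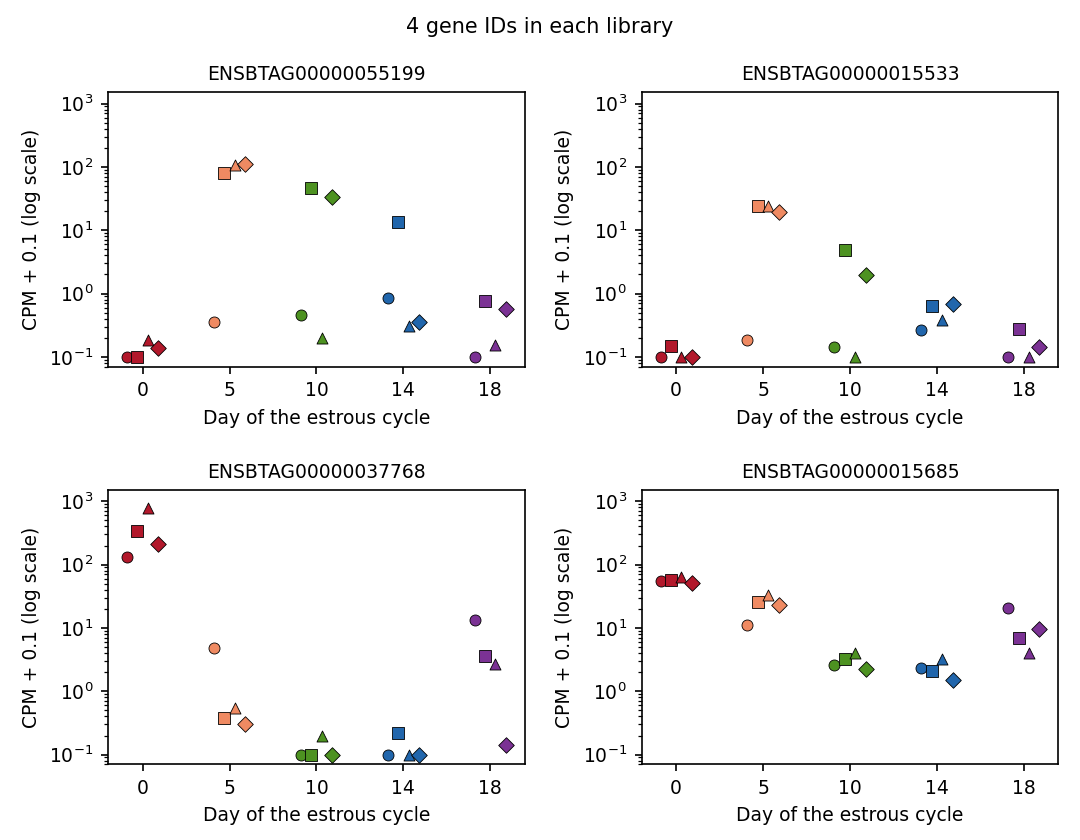
Expression of 4 gene IDs in each of the 20 libraries, by day of the cycle (vertical axis CPM + 0.1, log scale; color for the day, marker shape for the replicate number as in the plot of principal components). ENSBTAG00000055199 and ENSBTAG00000015533 are high in 3 of 4 day 5 libraries, ENSBTAG00000037768 averages 364 CPM on day 0, and ENSBTAG00000015685 is lowest on days 10 and 14.

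From day 5 to day 10, 1 gene passed the test. ENSBTAG00000015685 fell from 23.1 ± 9.19 to 2.90 ± 0.771 CPM (SD, n = 4 each), a log2 fold change of −2.99 (SE 0.43, edgeR adjusted p = 0.0371); it was chosen after its values were seen, as the single gene that passed. Its mean was 56.8 ± 5.66 CPM on day 0, 2.20 ± 0.728 on day 14 and 10.3 ± 7.25 on day 18, and from day 18 to day 0 it rose by a log2 fold change of 2.47 (SE 0.42, edgeR adjusted p = 0.00743). An unadjusted p under 0.05 was reached by 2246 genes, where chance alone gives 847, and in 8.21% of tested genes the 4 libraries of a day all lay above those of the other, where chance gives 2.86%. Genes of a library vary together, so such an excess need not come from the day. DESeq2 called 277 genes and limma voom with quality weights 1207. Leaving out day 5 replicate 1 raised the edgeR count to 34 and leaving out day 10 replicate 3 to 8; without day 5 replicate 2, 3 or 4 or day 10 replicate 1, 2 or 4 it was 0, as it was with only the 8 libraries of both days, with a 2-fold threshold and with a block for the replicate number. The adjusted p of ENSBTAG00000015685 ranged from 6.83e-09 to 0.351 over its 20 alternatives. In counts simulated for this step over 16798 genes, the edgeR test recovered 72% of genes changed by 4-fold and 29% of those changed by 2-fold. No library stood apart in the simulation, unlike day 10 replicates 1 and 3, so these shares need not hold for the real counts.

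No gene passed between day 10 and day 14 or between day 14 and day 18. From day 10 to day 14, 1397 genes had an unadjusted edgeR p under 0.05 where chance gives 847, while DESeq2 called 15 genes (5 rose, 10 fell) and limma voom with quality weights 22 (all fell). The count was 0 without any 1 of these 8 libraries. From day 14 to day 18, 1703 genes had an unadjusted edgeR p under 0.05, DESeq2 called 42 (33 rose, 9 fell) and voom 0; the edgeR count was again 0 without any 1 of the 8 libraries and 1 with only these 8 in the fit. Groups of 4 that did not overlap were seen for 5.33% of genes in the earlier step and 3.58% in the later, against 2.86% by chance. Such excesses need not come from the day, since genes of a library vary together. In simulated counts the test recovered 84% of 4-fold and 30% of 2-fold changes for day 10 to day 14 over 16785 genes, and 73% and 20% for day 14 to day 18 over 16794 genes. The simulation gave every day the same spread, unlike the real days 10 and 18, so these shares need not hold for the real counts.

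Closing the cycle, 297 genes rose and 182 fell from day 18 to day 0 by the edgeR test. Of the 35 divisions of these 8 libraries into 4 and 4, the real one gave 479 genes and 2 others gave 537 and 588, so chance cannot be excluded for this count or for the gene sets taken from it. Both of these others placed day 18 replicate 1 with 3 day 0 libraries. Of the genes that rose, 92 did so by at least 4-fold and 16 by at least 16-fold; of those that fell, 71 and 20 did. The median log2 fold changes were 1.41 and −1.52. The genes that rose into estrus had averaged −1.70 ± 0.239 on day 18 relative to day 0 in mean log2 CPM, −1.73 ± 0.0521 on day 14, −1.84 ± 0.276 on day 10 and −1.47 ± 0.180 on day 5 (SD, n = 4 libraries each); day 18 replicate 1 was at −1.38 and the other day 18 libraries at −1.95 to −1.70. Those called as falling into estrus averaged 1.66 ± 0.772 on day 18, with 0.554 in day 18 replicate 1 against 1.76 to 2.33 in the other 3, and 1.89 ± 0.0582 on day 14. Every mean is relative to the day 0 libraries used to choose the genes, so none is independent of the choice. Of the 479 called genes 62.0% rose; with scaling by total counts alone 466 genes changed and 45.9% of them rose. Leaving out day 18 replicate 1 raised the count to 2345, of which 1075 rose and 1270 fell (45.8% rose), so the balance of directions turned over; without any other of the 8 libraries 61.0% to 85.1% rose. Leaving out day 18 replicate 2, 3 or 4 lowered it to 172, 178 or 166, and day 0 replicate 1, 2, 3 or 4 to 105, 134, 249 or 158. With only the 8 libraries of both days in the fit it was 37, and against a 2-fold change it was 8. DESeq2 called 1637 genes (743 rose, 894 fell) and limma voom with quality weights 2068 (1200 rose, 868 fell).

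**Figure D4:**
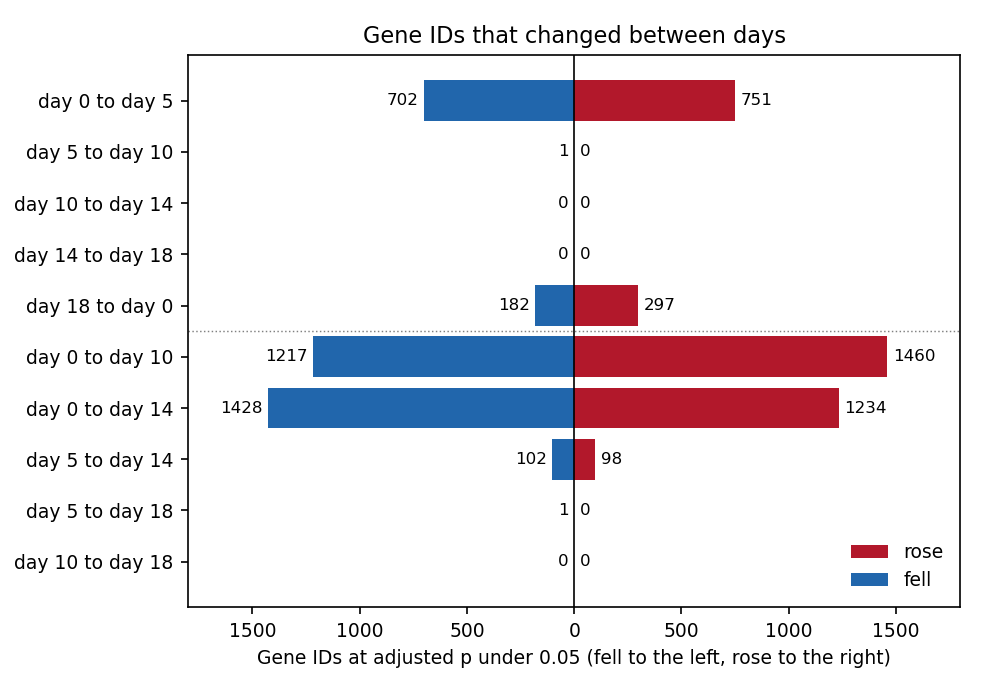
Gene IDs with an edgeR adjusted p under 0.05 for each pair of days (horizontal axis, number of IDs; fell to the left in blue, rose to the right in red); pairs above the dotted line are the 5 steps of the cycle. Counts exceed 1 from day 0 to day 5 and from day 18 to day 0, and in the other pairs for day 0 against days 10 and 14 and for day 5 against day 14.

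The genes called into and out of estrus overlapped in opposite directions, with the limit given above for the step from day 18 to day 0. Of the 297 that rose from day 18 to day 0, 227 fell from day 0 to day 5, where independent lists would share 12.3; of the 182 that fell, 89 rose again, where 8.07 would be shared; 0 moved the same way in both steps. Both steps use the same day 0 libraries, which alone ties their chance values together. With different pairs of day 0 libraries for each step, the 6 possible divisions gave 19 to 38 genes that rose and then fell, with at most 0.866 by independent lists, and 0 or 1 that fell and then rose. In these divisions only 7, 6, 3, 1, 0 and 0 genes were called as falling from day 18 to day 0, so for the 89 genes that fell and rose again there is no check free of the shared libraries. Across all tested genes the log2 fold changes of the 2 steps had a covariance of −0.442, against −0.131 on average in 20 simulations without any change, a difference of −0.312. The simulated value depends on the spread assumed for day 0. In the 6 divisions with no day 0 library shared between the steps, the covariance was −0.371 to −0.407.

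Across all 5 days, 1911 genes (11.3% of those tested) changed in a single edgeR test of the differences between days. Their fitted means differed by at least 4-fold between days in 764 genes and by at least 16-fold in 233. For 1622 of them (84.9%), the highest or the lowest mean fell on day 0, against 40% if each day were equally often an extreme and 59.6% among all tested genes. The share was 73.9% without day 5 replicate 1 and 92.9% without day 5 replicate 3, the ends of its range with each library left out. Day 0 held the highest mean of 867 genes and the lowest of 755. The highest mean fell on day 5 in 327 genes, on day 10 in 362, on day 14 in 284 and on day 18 in 71. Leaving out day 0 replicates 1, 2, 3 or 4 lowered the count to 822, 700, 906 or 737, day 5 replicates 2, 3 or 4 to 1057, 1164 or 1219 and day 14 replicates 1, 2 or 3 to 1187, 1213 or 1091. Without day 18 replicate 1 it was 3977.

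The other 5 pairs of days were compared after the data had been examined. From day 0 to day 10, 1460 genes rose and 1217 fell, and from day 0 to day 14, 1234 rose and 1428 fell. Between days 5 and 14, 98 genes rose and 102 fell, with 43 of the falls and 4 of the rises by at least 4-fold. Between days 5 and 18, 1 gene fell (0 with a block for the replicate number), and from day 10 to day 18, 0 genes passed. In these 2 pairs 2426 and 1383 genes had an unadjusted edgeR p under 0.05, where chance gives 847. Groups of 4 that did not overlap were seen for 3.92% and 1.62% of genes, against 2.86% by chance. Genes of a library vary together, so an excess over 847 need not come from the day. DESeq2 called 536 and 89 genes, and voom 1076 and 1. With scaling by total counts alone, the share that rose was 68.3% instead of 54.5% from day 0 to day 10, 73.5% instead of 46.4% from day 0 to day 14, and 19.4% (of 103 genes) instead of 49% (of 200) from day 5 to day 14. The count from day 0 to day 10 was 1437, 1252, 1718 or 1560 without day 0 replicate 1, 2, 3 or 4 and 1424 without day 10 replicate 1, and 46.6% to 49.2% of the genes rose without a day 0 library. The count from day 0 to day 14 was 1515, 1016, 1438 or 1643 without day 0 replicate 1, 2, 3 or 4 and 1225, 1289 or 1115 without day 14 replicate 1, 2 or 3. For day 5 to day 14 it was 866 without day 5 replicate 1 and 2 to 4 without any other of the 8 libraries. For day 5 to day 18 it was 418 without day 5 replicate 1, 438 without day 18 replicate 1, 2 without day 18 replicate 2 or 3 and 0 without replicate 4. From day 10 to day 18 it was 33 without day 10 replicate 3.

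Each library was also placed between day 14 and day 0 on 5793 genes, chosen as changed between those days in a fit of their 8 libraries alone, with the mean of day 14 set to 0 and that of day 0 to 1. Day 5 libraries averaged 0.376 ± 0.060, day 10 libraries 0.146 ± 0.150 and day 18 libraries 0.382 ± 0.356 (SD, n = 4 each). All 4 day 10 libraries lay below all 4 day 5 libraries, although day 10 replicate 3 was at 0.332 and day 5 replicate 2 at 0.333. This order held on the genes higher on day 0 but not on other gene sets. On genes at edgeR adjusted p under 0.01, day 10 replicate 3 (0.352) lay above day 5 replicates 1 and 2 (0.342 and 0.335). On genes lower on day 0 it was at 0.482, above all 4 day 5 libraries (0.298 to 0.403). The difference between days 5 and 10 was −0.230, with p = 0.0286 by a two-sided exact permutation test and 0.0857 after adjustment over 3 pairs of days, so it did not pass 0.05. Between days 10 and 18 the exact permutation p was 0.314 and between days 5 and 18 it was 1. Within day 18, replicate 1 lay at 0.877, replicate 2 at 0.181, replicate 3 at 0.394 and replicate 4 at 0.0745.

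**Figure D5:**
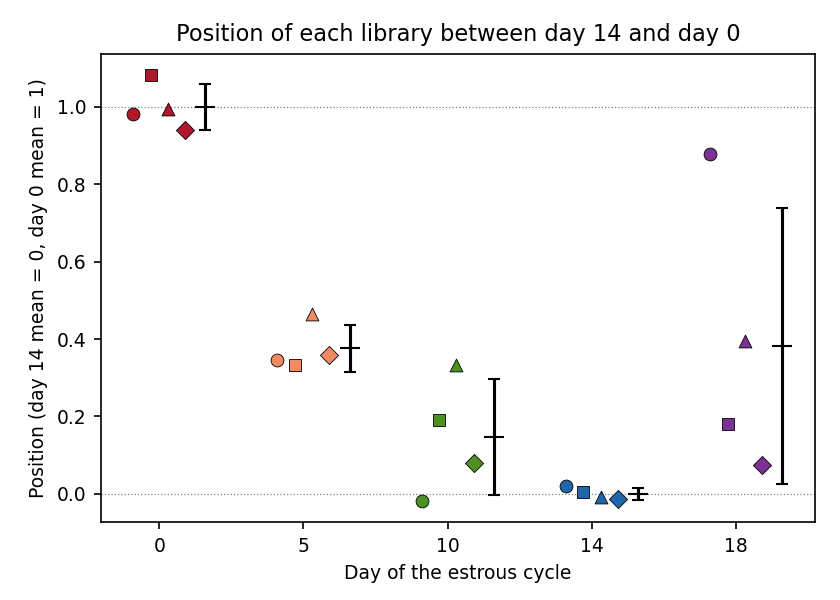
Position of each library between the mean of day 14 (0) and the mean of day 0 (1) on 5793 genes (vertical axis, no unit), by day; points are the 4 libraries of a day and the bars beside them the mean ± SD. Days 14 and 0 are fixed by construction, day 5 averages 0.376, and day 18 spans 0.0745 to 0.877.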

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

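Of the tests of explanations in this part, the exchange of labels with day 0, the tests of admixture against libraries outside the 3 and of day 18 replicate 3 by itself, the tests of day 18 replicate 1 with day 0 libraries kept out, and the count from day 5 to day 10 without 4 libraries were chosen after the result was seen. Values per library were screened for a library whose gap to its nearest neighbour, divided by the range of its day, lay above Dixon's 95% critical value for 4 samples. Over 73 groups of 4 libraries, 8 were found. In 3 of them 1 library had 1 to 3 counts and the others 0, which puts the gap at the whole range by construction; in the other 70 groups, 5 were found where chance gives about 3.5 for normally distributed values, and many of the groups share libraries and genes. Day 5 replicate 1 had a median correlation of 0.929 with its own day, where the other 3 had 0.975. Day 14 replicate 4 had 0.943, where the others had 0.973 to 0.979. The mean correlation of day 5 replicate 1 was 0.927 with its own day, 0.939 with day 14 and 0.930 with day 18. With days 0 and 10 it was lower, at 0.925 and 0.908. In the genes that fell from day 0 to day 5, day 14 replicate 4 averaged −1.10 in log2 CPM relative to day 0, and the others −1.22 to −1.21. ENSBTAG00000055199 was at 13.2 CPM in day 14 replicate 2 and at 0.206 to 0.758 CPM in the others. ENSBTAG00000015533 was at 0.0492 CPM, a single count, in day 0 replicate 2 and at 0 in the others. ENSBTAG00000037768 was at 4.78 CPM in day 5 replicate 1 and at 0.206 to 0.445 in the others, at 0.0990 CPM (2 counts) in day 10 replicate 3 with 0 in the others, and at 0.115 CPM (3 counts) in day 14 replicate 2 with 0 in the others.

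Day 10 replicates 1 and 3 and day 18 replicate 3 lay apart from the other 17 libraries on the first principal component, by 69.7 score units. Depth and a few abundant genes are argued against: thinned to 21234000 counts each, the libraries kept a gap of 69.7, and 1813 genes (811 higher, 1002 lower) had all 3 libraries beyond the other 17, where the 95th percentile of 200 random sets of 3 was 93. The 3 libraries were picked as extremes of these same values, which favours an excess over random sets. Only the number of genes itself therefore speaks against a few abundant genes. Admixture of other cells alone would dilute the remaining genes alike, so few genes should lie at least 4-fold below every other library of the day. These numbered 278, 270 and 467 in the 3 libraries and up to 444 (day 5 replicate 1) in the other 17, but day 10 replicates 1 and 3 hide each other's falls in this count. Against the 2 day 10 libraries outside the 3 they had 1021 and 889 such genes, where the other 17, each against up to 2 libraries of its day outside the 3, had at most 542 (day 18 replicate 1). In day 10 replicates 1 and 3, admixture alone is therefore argued against, unless the other cells supplied most of the RNA, which was not tested. Day 18 replicate 3 had 555 to 890 against pairs of libraries of its day, also above 542. Its highest number is close to the 889 of day 10 replicate 3, the library it correlated with best. The excess of 467 over 444 and that of its lowest number, 555, over 542 are within counting error. Genes of a library vary together, so counting error understates the uncertainty of all these numbers. The limits of 444 and 542 come from day 5 replicate 1 and day 18 replicate 1, which themselves stand out from their days here. Without them, the highest numbers in the rest of the 17 were 148 and 267, both in day 14 replicate 4. Admixture stays open in day 18 replicate 3, since the outcome depends on the libraries that set the limit and there are no markers to test it. The different reading of day 10 replicate 3 and day 18 replicate 3 rests on which pair is compared and on that limit. The 3 libraries come from 2 days, so the day of the cycle alone does not part them; differences between animals or in the biopsied site were not tested.

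Day 18 replicate 1 lay with the day 0 libraries, with a mean r of 0.946 to day 0 and 0.895 to its own day. Its best match was day 0 replicate 2 (r = 0.956), but day 5 replicate 1 came next (r = 0.953). Day 0 replicates 1, 3 and 4 followed at 0.938, 0.948 and 0.942. The tie to day 5 replicate 1 was not tested. A simple exchange of labels with a day 0 library is argued against: 0 day 0 libraries correlated better with day 18 replicates 2 and 4 than with each other. On genes chosen from days 0 and 14 alone its position was 0.877, with 0.764 on the genes higher on day 0 and 0.978 on those lower. A prediction fixed before this test put an animal back in the day 0 state, or mislabelled, nearer day 0 than day 14. It was met on all genes and on both subsets. The day 0 libraries helped to choose these genes, so each was also kept out in turn. On genes changed between days 0 and 14 the libraries kept out lay at 0.874 to 1.05 (lower 95% prediction limit 0.654) and day 18 replicate 1 at 0.846 to 0.887. On those lower on day 0 the values were 0.842 to 1.06 and 0.946 to 0.986. On those higher on day 0 they were 0.893 to 1.05 (limit 0.675) and 0.716 to 0.782. On genes changed between days 0 and 5, day 5 was set to 0 and day 0 to 1. There the libraries kept out lay at 0.864 to 0.941 (lower 95% prediction limit 0.787), day 18 replicate 1 at 0.651 to 0.717 and the other day 18 libraries at 0.389 or less. Over all tested genes, 154 to 222 were at least 4-fold below 3 of the day 0 libraries in day 18 replicate 1, and 10 to 21 in the remaining day 0 library. The genes changed between days 0 and 5 and the genes at least 4-fold below argue against a library in the full state of day 0. This covers an early return and a wrong label. The genes changed between days 0 and 14 do not argue against it. The values are consistent with a library between the other day 18 libraries and day 0, as a hypothesis found on the same data; whether by a partial return to estrus or by a wrong label of an animal near estrus was not tested.

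Between days 5 and 10 the edgeR test called 1 gene, although 2246 had an unadjusted p under 0.05. Without the 3 libraries apart on the first component and day 18 replicate 1, it called 163 (115 rose, 48 fell), and the 1 gene was among them. Wide spread between these libraries may therefore limit the count, as a hypothesis found and tested on the same data. The same omission raised the count from day 0 to day 5 (1453 to 4095) and from day 18 to day 0 (479 to 3216). From day 14 to day 18 it stayed at 0, and from day 10 to day 14 it became 1. The rise is therefore not particular to days 5 and 10. Without only the 3 libraries the count from day 5 to day 10 was 8, and day 10 then kept 2 libraries in both fits. The further rise to 163 came with leaving out day 18 replicate 1, which is of neither day.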

How the results depend on the processing

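Counts without 3 or 4 libraries, the settings for abundant IDs, the permutations of replicate numbers and the gene sets for the position of day 18 replicate 1 were chosen after seeing the data. No fold change of a printed ID reversed. Every count kept within 1.5 times of its value with RLE factors, total counts alone, either other low-count filter or no robust option, for the 5 steps and the 5 days together. The causes of the moves below were not tested. From day 0 to day 5 (1453 genes) a 2-fold threshold gave 55, voom 5796, DESeq2 2550, only the 8 libraries 3519, without 3 libraries 3069 and without 4 libraries 4095. From day 5 to day 10 (1 gene) a 2-fold threshold and only the 8 libraries gave 0, voom 1207, DESeq2 277, without 3 libraries 8 and without 4 libraries 163. From day 10 to day 14 (0) voom gave 22, DESeq2 15 and without 4 libraries 1. From day 14 to day 18 (0) DESeq2 gave 42 and only the 8 libraries 1. From day 18 to day 0 (479) a 2-fold threshold gave 8, voom 2068, DESeq2 1637, only the 8 libraries 37 and without 4 libraries 3216. Across the 5 days (1911) voom gave 9386, DESeq2 5076, without 3 libraries 3556 and without 4 libraries 6127. With each library of the days left out in turn, the counts ranged from 434 to 1378, 0 to 34, 0 to 0, 0 to 0 and 105 to 2345 for the 5 steps in order, and from 700 to 3977 across the 5 days. For the other 5 pairs (day 0 to 10, 0 to 14, 5 to 14, 5 to 18 and 10 to 18, with 2677, 2662, 200, 1 and 0 genes) voom gave 4850, 8214, 5870, 1076 and 1, DESeq2 4032, 3974, 1358, 536 and 89, a 2-fold threshold 160, 124, 0, 0 and 0, only the 8 libraries 1957, 5793, 1893, 0 and 0, without 3 libraries 1755, 4400, 938, 1 and 1, and without 4 libraries 3152, 5924, 2940, 863 and 3. With no low-count filter day 5 to day 14 gave 23, and with total counts alone 103. DESeq2 called 1451 and voom 1444 of the 1453 genes from day 0 to day 5, and 476 and 448 of the 479 from day 18 to day 0, all in the same direction. DESeq2 gave no adjusted p for 5449 IDs from day 0 to day 5. The share of genes with an extreme at day 0 was 67.1% with voom, 78.9% without 3 libraries, 74.1% without 4, and 73.9% to 92.9% with each library left out. The call of ENSBTAG00000055199 was lost under 4 of 19 alternatives and that of ENSBTAG00000015685 under 9 of 20. In the fit of only the 8 libraries of days 0 and 5, ENSBTAG00000055199 and ENSBTAG00000015533 were removed by the low-count filter and not tested. The gene list tests and the epithelium covariate were not run, since they need gene names. At these depths, changes from or to 1 to 3 counts are bounded only by their counting intervals.

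The replicate numbers were not treated as pairs, since animals were assigned to a day at random. Deviations from the day's mean correlated with a median of 0.046 over the 40 pairs with the same number on different days (range −0.374 to 0.766) and −0.022 over the 120 with other numbers. Of 20 libraries 10 matched their own number best, where 2000 permutations of the numbers within days gave 5.07 on average (one-sided p = 0.0405; 0.0715 for the median), so a weak tie between libraries of the same number is not excluded. With the replicate block the counts were 1777, 0, 0, 0 and 374 for the 5 steps in order and 2078 across the 5 days; from day 5 to day 14 it gave 373 instead of 200, and from day 5 to day 18 0 instead of 1, so that call was lost.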

Other observations

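The grouping of libraries for the counts below was tested as planned; the 5 pairs of days outside the steps were chosen after the data had been examined, and the values in the second paragraph were singled out after they were seen. Every other division of the 8 libraries of a comparison into 4 and 4 was run through the same edgeR test. From day 0 to day 5, 1 of 35 divisions, the real one, gave as many as 1453 genes, and the highest other gave 0, so chance is argued against for this comparison taken alone. The same held for day 0 to day 10 (1 of 35, 2677 genes, highest other 0), day 0 to day 14 (1 of 35, 2662 genes, highest other 0) and day 5 to day 14 (1 of 35, 200 genes, highest other 21), although the last count was 2 to 4 without any 1 of its 8 libraries other than day 5 replicate 1, and 866 without that library. A share of 1 in 35 is 0.0286, the smallest possible here, and after adjustment over the 10 pairs of days it is 0.0714, which does not pass 0.05. Across the 5 days, 1 of 100 groupings, 99 of them drawn at random, gave 1911 genes, and the highest other gave 245, so chance is argued against. Chance cannot be excluded from day 18 to day 0, where 3 of 35 divisions gave at least 479 genes and the highest other 588; both of the others placed day 18 replicate 1 with 3 day 0 libraries. It cannot be excluded from day 5 to day 10 (6 of 35, 1 gene, highest other 97) or day 5 to day 18 (6 of 35, 1 gene, highest other 650). For day 10 to day 14, day 14 to day 18 and day 10 to day 18 the edgeR count was 0, so each division necessarily gave as many (35 of 35) and nothing follows about chance; the highest other gave 0, 17 and 3104. The division with 3104 genes put day 10 replicates 1 and 3 and day 18 replicates 1 and 3 against the other 4 libraries, which points to a structure of these libraries other than the day. The divisions with 97 and 650 genes set day 5 replicate 1 with 3 libraries of the later day, which points to a structure of these libraries whose nature was not tested. The division with 650 genes is the one that an exchange of labels between day 5 replicate 1 and day 18 replicate 1 would give. Exchanges of day 5 replicate 1 with day 18 replicates 3, 2 and 4 gave 568, 43 and 26 genes. On the genes changed between days 0 and 14, day 18 replicate 1 lay at 0.877, against 0.333 to 0.464 in day 5 replicates 2, 3 and 4. It correlated with these day 5 libraries at r = 0.909 to 0.920, while they correlated with each other at 0.975 to 0.977. These values argue against an exchange of day 5 replicate 1 with day 18 replicate 1. Whether day 5 replicate 1 was exchanged with another day 18 library was not tested.

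The 751 genes that rose by day 5 averaged 1.26 above day 0 in log2 CPM in day 5 replicate 1, and 1.82 to 2.32 in the other day 5 libraries. Among day 10 libraries they averaged 1.77, 1.55, 1.09 and 1.52 in replicates 1 to 4, and among day 18 libraries 0.404, 1.22, 0.783 and 0.876. Day 5 replicate 1 had 444 genes at least 4-fold below every other library of its day, against 4 to 24 in the others.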
